A study of Mus musculus with 2 samples.

How the data were processed

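The series compared a GATA1 ChIP-seq library with a chromatin input library, both from G1E-ER4 cells induced with 20 nM estradiol for 24 h. Per the labels' protocols, sonicated chromatin was precipitated with a GATA1 antibody, adapters were ligated, the DNA was amplified for 18 PCR cycles, fragments of about 250 bp including adapters were cut from a gel and sequenced on an Illumina Genome Analyzer. Each group had 1 library, and samples were grouped by the labels' statement of what was precipitated.

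The authors deposited 2 tables of aligned reads and 1 list of peaks. The aligned tables have no header. They give each 36-base read with 1 position, its strand, a description of its mismatches and an alignment score set by the authors' aligner. The deposited peak list gives chromosome, start, end, name and a score per peak, whose scale the file does not name. The score is the authors' and was used only to rank peaks within the list. Peak names begin with MACS, the name of a peak caller. The genome build was mm8, per the submitters' processing notes. The aligner, the caller's version and their settings were not given in the sources used here.

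Reads were counted with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0, and figures drawn with matplotlib 3.10.9. The distance at which forward and reverse read ends coincided most often was found in steps of 5 bp over peaks, from a running mean over 5 steps. It was 100 bp for the ChIP library (105 bp without the running mean), and every read of both libraries was moved inwards by 50 bp before counting in peaks. Counts per peak were divided by the ChIP to input ratio of reads outside peaks, 1.49, after adding a pseudocount of 1 read. Limits of each ratio are exact conditional binomial limits at 95%, from the counts without the pseudocount, so the printed ratio and its limits differ in that respect. Shares have exact Clopper-Pearson 95% intervals and medians have order-statistic intervals. These libraries were amplified by PCR and reads carry no molecular identifiers, so intervals cover counting error only. Distinct positions made up 96.7% of the ChIP reads and 98.0% of the input reads. The ChIP reads came from 3 lanes with 9951624, 9612699 and 4293824 reads, and the input reads from 2 lanes with 7664418 and 7987405. Lanes were pooled as 1 library per group and never treated as replicates, although the labels do not say whether ChIP run 7 lane 1 came from a separate preparation.

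A genome of the authors' build was not used here, so the sequence around peaks was rebuilt from the reads of both libraries, with each mismatched base replaced by the reference base that the alignment records. The 76102953 bases laid down in this way showed 0 disagreements. They covered 93.8% of the central 200 bp of peaks and 49.4% of windows 1000 bp away, and 10919 peaks had at least 90% of their centre covered. Because flanks were covered less, motif densities are per kb of sequence read, and shares of windows were compared over positions read in both. Flank sequence inside another listed peak was left out. Intervals of density ratios are normal approximations from the numbers of sites. Coordinates of motif sites count from 1, as the aligned reads do.

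Because no gene annotation in build mm8 was used, peaks were not assigned to genes. The planned comparisons with transcription starts, with 12 fixed gene lists and with named genes were therefore not made. The supplied gene table is for another build and its coordinates were not used. The rule for named peaks, the 10 with the most ChIP reads, was fixed before the data were examined, as were WGATAR, the 7 partner motifs and the ranking of peaks. The spacing scan, the search over all 6-base sequences, the forms of WGATAR, the classes of motif content, the chains of peaks and the cells' own sequence were added afterwards. Summits are centres of the 51 bp window with the most ChIP fragment midpoints in the peak.

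The cells' own bases were read from the mismatches. A position within 250 bp of a peak centre was called where at least 5 reads covered it and at least 90% agreed. Only counts of sites are given.

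The scripts were tested on simulated data. With 200 of 14351 peaks raised in the ChIP to input ratio, 56.5% of 4-fold and 88.5% of 8-fold changes had a lower limit above 1, and so did 0.763% and 0.685% of unchanged peaks. With AGATAA placed in 1200 of 4000 random windows, 52.0% of windows had WGATAR where 52.1% had been built to, and CTG placed before some of them was found at its gap of 8 bp. Of 80 sites present only in simulated cells, 58 were called as gained and 0 sites as lost, with 69.4% of positions covered well enough to call. The alternatives tried were 1 read per position, reads without mismatches, another scaling, other pseudocounts, other windows and motifs, other rankings, single lanes and the better-scoring peaks. Their effects are in the closing section.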

Results

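GATA1 occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in G1E-ER4 cells, a mouse erythroid precursor line that lacks its own GATA1 and carries a GATA1 fused to the ligand-binding part of the oestrogen receptor. GATA1 is the zinc-finger transcription factor that drives red cell maturation, and estradiol makes the fusion protein active. The cells had been exposed to 20 nM estradiol for 24 h. The GATA1_ChIP group held 1 library and the input group, chromatin sequenced without immunoprecipitation, held 1 library. The ChIP library had 23858147 aligned reads and the input library 15651823. With 1 library per group there were no replicates, so no test between conditions was made and the intervals below cover counting error only.

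The first question was how many places in the genome GATA1 occupied and how much of the ChIP library came from them. The authors' list held 14351 peaks that together spanned 6069152 bp. Peaks had a median width of 395 bp and ranged from 150 to 2990 bp. They held 2.37% of the ChIP reads (566257 reads, exact 95% interval 2.37 to 2.38) and 0.351% of the input reads (54957 reads, interval 0.348 to 0.354), a 6.76-fold difference in share. The median peak had 28 ChIP reads and 3 input reads, and 933 peaks had no input read. In peaks, forward and reverse ChIP read ends lined up best about 100 bp apart after smoothing over 25 bp, the pattern of fragments that surround a bound site. Input read ends in peaks were too few to show a clear maximum, with 314 pairs at 70 bp, 311 at 20 bp and 306 at 30 bp.

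Each peak was then set against input, which gives how far the ChIP library exceeded the background at each place. The median ChIP to input ratio was 4.91 (95% interval of the median 4.82 to 4.91), on a scale in which reads outside peaks have a ratio of 1 and with a pseudocount of 1 read. A ratio of at least 2 was reached by 14184 peaks (98.8%), of at least 5 by 6985 peaks (48.7%), of at least 10 by 2346 peaks (16.3%) and of at least 20 by 444 peaks (3.09%). For 13294 peaks (92.6%, exact interval 92.2 to 93.1) the lower 95% limit of the ratio was above 1. The authors had listed the peaks from these same ChIP reads, so the ratios and limits are raised by that selection and are not an independent test of the list. This share depended on depth, since with the reads of ChIP run 7 lane 1 only it was 53.6%. The median ratio was 2.68 with a pseudocount of 5 reads, because most peaks had so few input reads.

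**Figure D1:**
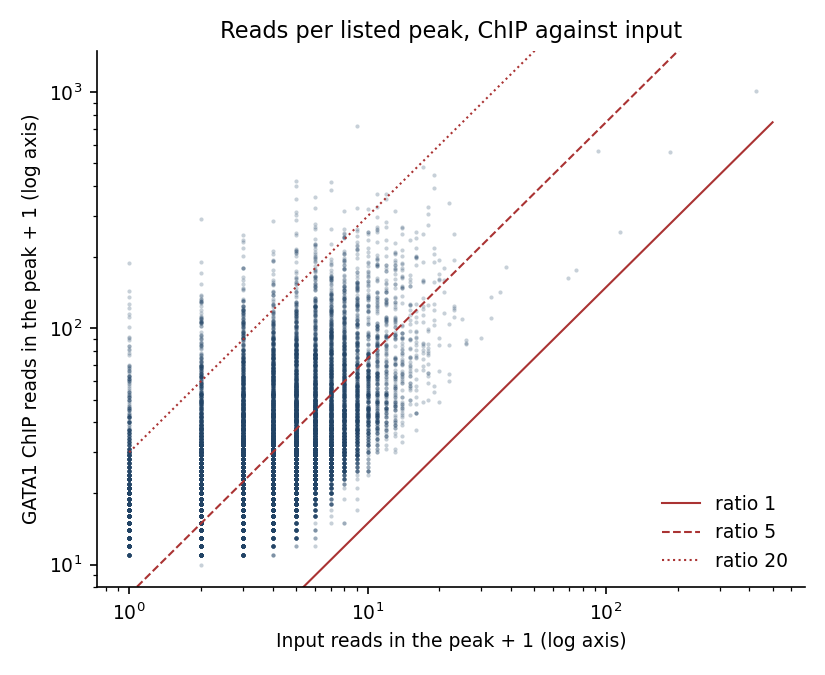
Input reads (x, log axis) and GATA1 ChIP reads (y, log axis) in each of the 14351 listed peaks, each with 1 read added; lines mark ratios of 1, 5 and 20 after scaling to reads outside peaks. Every listed peak lay above the line of ratio 1, and 10 peaks with at least 30 input reads lay to the right of the rest.

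The 10 peaks with the most ChIP reads fell into separate kinds (all positions are in build mm8, as listed by the authors, whose file does not say whether starts count from 0 or from 1). Genes were not assigned here. MACS_peak_117 on chromosome 1 from 36864106 to 36865400 had 718 ChIP reads and 8 input reads, a ratio of 53.5 (exact 95% limits 30.3 to 140), and the highest of the authors' scores, 3100. The WGATAR motif (A or T, then GATA, then A or G) nearest to its summit was a TGATAA on the reverse strand at 36864578 to 36864583, within the sequence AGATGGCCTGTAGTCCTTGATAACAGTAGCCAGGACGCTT. MACS_peak_2467 on chromosome 11 from 95172277 to 95173394 had 421 ChIP and 4 input reads (ratio 56.5, limits 27.3 to 260), with a reverse-strand AGATAA at 95172685 to 95172690 in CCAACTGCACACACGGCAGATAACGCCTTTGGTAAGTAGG. MACS_peak_5248 on chromosome 16 from 32428822 to 32429868 had 399 ChIP and 4 input reads (ratio 53.6, limits 25.9 to 246), with a forward-strand TGATAA at 32429513 to 32429518 in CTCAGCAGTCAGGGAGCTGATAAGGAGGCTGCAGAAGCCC. MACS_peak_2196 on chromosome 11 from 72297818 to 72299012 had 416 ChIP and 6 input reads (ratio 39.9, limits 21.2 to 127), and its nearest motif was a TGATAG at 72298344 to 72298349.

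Also among those 10 were MACS_peak_12130 on chromosome 7 from 80081528 to 80083091 (480 ChIP reads, ratio 18.9), MACS_peak_12802 on chromosome 8 from 35565500 to 35567337 (444 ChIP reads, ratio 15.7) and MACS_peak_614 on chromosome 1 from 135641704 to 135642696 (391 ChIP reads, ratio 13.8). Each had an AGATAA within 6 bp of its summit, and in MACS_peak_614 the surrounding sequence was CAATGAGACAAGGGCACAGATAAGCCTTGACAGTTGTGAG. The other 3 peaks were high in both libraries. MACS_peak_14182 on chromosome 9 from 123780319 to 123783309 had the most ChIP reads of any peak, 1015, but also 425 input reads, a ratio of 1.60 (limits 1.43 to 1.80). MACS_peak_2710 on chromosome 11 from 108827621 to 108828415 had 560 ChIP and 184 input reads (ratio 2.03), and MACS_peak_10801 on chromosome 6 from 3151245 to 3151736 had 563 ChIP and 92 input reads (ratio 4.06). No WGATAR was found within 100 bp of the summits of MACS_peak_2710 and MACS_peak_10801, although only 56% of the centre of the latter could be read.

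Where peaks lay along the genome was described by chromosome and by distance between neighbours. Chromosomes 11 and 19 had the most peaks for their input, with 14.9 peaks per 10000 input reads (95% interval 14.1 to 15.8) and 14.7 (13.4 to 15.9), followed by chromosome 17 with 11.6 (10.7 to 12.6). The autosomes together had 9.28. Chromosome X had the fewest, 4.78 (4.09 to 5.56), then chromosome 14 with 5.92 (5.40 to 6.49) and chromosome 1 with 6.82 (6.40 to 7.25). Input depth differed between chromosomes. Relative to the autosomes' median, chromosome X had 0.367 times the input reads per Mb and chromosome 1 had 1.31 times, and the median ratios of their peaks were 6.998 and 4.15.

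**Figure D2:**
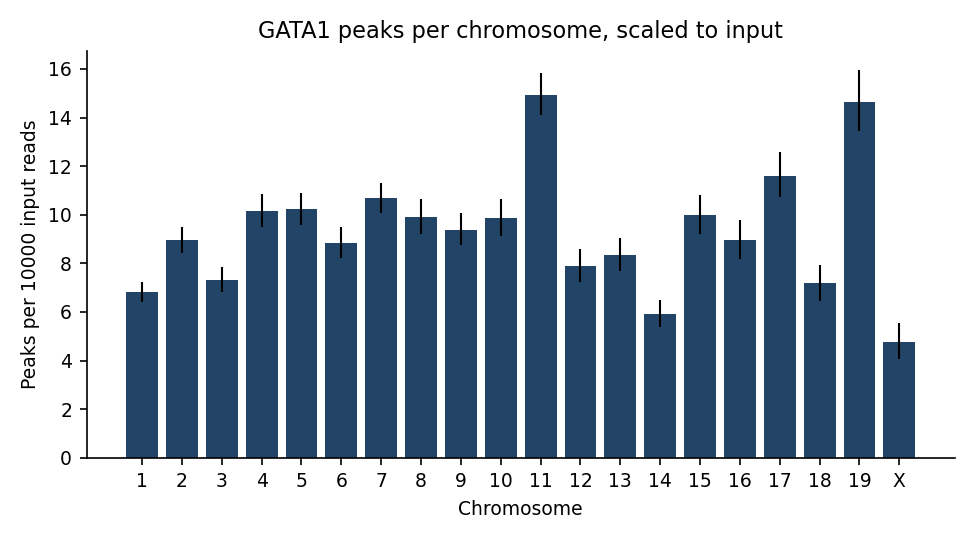
Listed GATA1 peaks per 10000 input reads (y) for each chromosome (x); bars are the 1 ChIP library's peak list and error bars 95% counting intervals. Chromosomes 11 and 19 stood highest, at 14.9 and 14.7, and chromosome X lowest, at 4.78.

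Peaks gathered in groups. Of neighbouring peaks, 4543 pairs lay within 10000 bp of each other, against a mean of 1089 (highest 1128) in 20 random draws of as many input read positions per chromosome. Chains of at least 5 peaks with such spacing numbered 221 and held 1341 peaks, while the random draws gave a mean of 7.05 chains (highest 10). The longest chain had 14 peaks on chromosome 19 between 24578098 and 24627573, with 637 ChIP and 48 input reads in all. Chains of 12 peaks lay on chromosome 8 between 123348086 and 123384829, on chromosome 2 between 31937735 and 31986928, and on chromosome 7 between 135413978 and 135447698. Peaks in chains of at least 5 had a median ratio of 5.74 (95% interval 5.36 to 6.03), and the 7199 peaks with no neighbour in reach had 4.52 (4.46 to 4.69).

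The sequence that GATA1 recognises was then looked for in the peaks. WGATAR occurred in the central 200 bp of 10952 of the 14351 peaks (76.3%, exact interval 75.6 to 77.0). Its density there was 6.92 sites per kb of sequence read, against 2.04 per kb in flanks 800 to 1900 bp away, a ratio of 3.39 (95% counting interval 3.33 to 3.45). Windows 1000 bp to each side were only partly covered by reads. Over the positions searched in both, 44.1% of the central windows and 15.4% of the flanking windows had a WGATAR. The motif sat close to the point of highest ChIP signal. Density reached 12.9 per kb in the 25 bp before the pileup summit and 12.7 in the 25 bp after it, and fell to 2.39 per kb at 150 bp after it. The nearest WGATAR was at a median of 23.5 bp from the summit and 38.5 bp from the listed centre, and 71.6% of peaks had one within 50 bp of the summit.

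**Figure D3:**
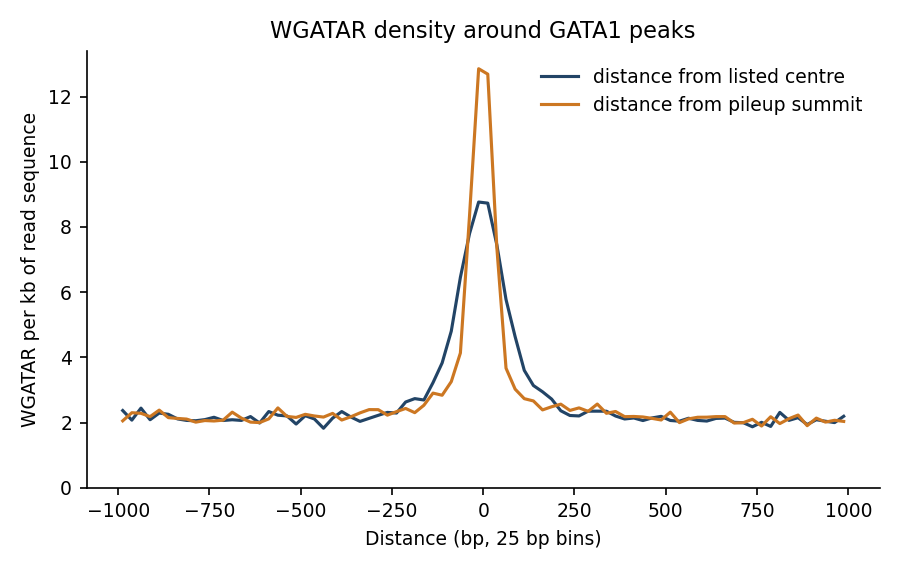
WGATAR sites per kb of sequence read (y) in 25 bp bins by distance in bp (x) from the listed peak centre and from the pileup summit of ChIP reads, over 14351 peaks. Density around the summit reached 12.9 per kb, above the 2.04 per kb of the flanks.

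A search that assumed no motif gave the same core. Among all 2080 sequences of 6 bases (each with its reverse complement), GATAAG had the highest ratio of peak centre to flank, 6.53 (6.29 to 6.77), followed by AGATAA with 4.97 (4.82 to 5.13) and CGATAA with 4.07 (3.65 to 4.53). Of the top 20, 17 contained GATA. The forms of WGATAR differed, as AGATAA (4.97) and TGATAA (3.61, interval 3.48 to 3.75) were more enriched than AGATAG (2.35, 2.25 to 2.44) and TGATAG (2.09, 1.99 to 2.20). Adding a G made AGATAAG 8.69-fold denser at peak centres than in flanks (8.24 to 9.17). At the other end, TATATA had a ratio of 0.376 and AATATA 0.386.

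Peaks with more ChIP reads in their span more often had the motif. Ranked by ChIP reads, 56.8% of the lowest quintile of peaks had WGATAR (54.9 to 58.6), and the following quintiles had 76.4%, 81.7%, 84.8% and 82.0%, the last below the one before it. The highest exceeded the lowest by 25.2 percentage points (22.9 to 27.5). Peaks are not replicates, and the interval describes this list. Less of the sequence could be read in the lowest quintile, 88.5% against 97.3% in the highest. Among the peaks whose central 200 bp were read in full, a set chosen after the data were seen, the difference was 15.1 points (11.9 to 18.3). Those peaks were divided into quintiles anew, so their quintiles are not those of the whole list. The smaller difference can therefore not be put down to unread sequence alone. The median ratio was 4.19 (4.02 to 4.24) in the 3399 peaks without WGATAR, 5.02 (4.91 to 5.02) in the 5668 with 1 site, 5.19 (5.11 to 5.36) in the 3963 with 2 sites and 5.36 (5.02 to 5.58) in the 1321 with 3 or more.

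**Figure D4:**
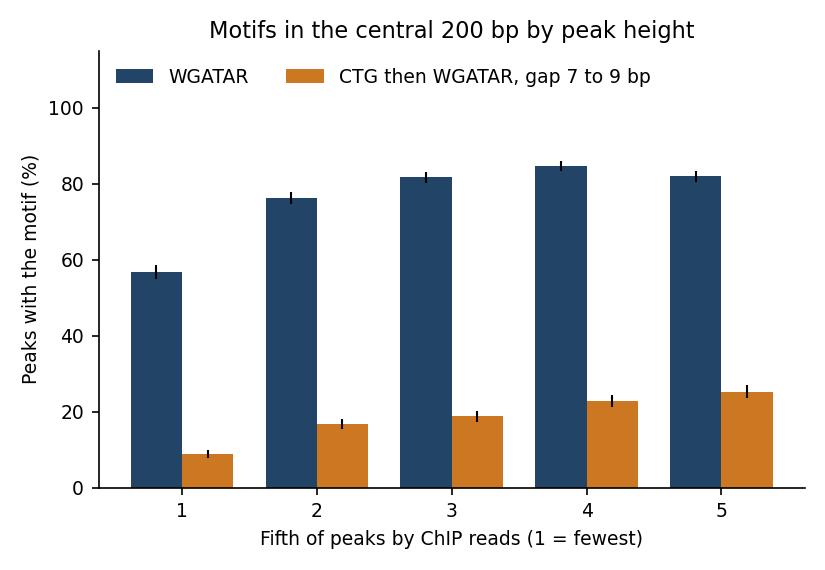
Percentage of peaks (y) whose central 200 bp held WGATAR, or CTG followed by WGATAR after a gap of 7 to 9 bp, by quintile of ChIP reads (x, 1 = fewest); error bars are exact 95% intervals. WGATAR went from 56.8% to 82.0% and the CTG pair from 8.92% to 25.3%.

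The last comparison asked which partner motifs accompanied GATA1. TAL1, which binds E-boxes (CANNTG) with its partner E proteins, is held in erythroid complexes with GATA1 by LMO2 and LDB1. E-boxes by themselves were barely denser at peak centres than in flanks, with a ratio of 1.07 (1.05 to 1.09). An E-box followed by WGATAR after 7 to 9 bp had a ratio of 7.99 (7.06 to 9.04), which includes the 3.39 of WGATAR by itself, and occurred in 716 peaks (4.99%, exact interval 4.64 to 5.36). Per WGATAR site, E-boxes were more frequent at peak centres than in flanks by a factor of 1.9999 at 7 bp (1.61 to 2.48), 2.98 at 8 bp (2.46 to 3.62) and 1.65 at 9 bp (1.31 to 2.08). The value at 9 bp did not stand apart. E-boxes 1 bp after WGATAR had a factor of 1.77 (1.43 to 2.18), and those 14 bp before it 1.64 (1.27 to 2.12). Spacings were also scanned for CAG, for a further WGATAR in either orientation and for CTG, the part of the E-box nearer to WGATAR. CTG stood 8 bp before 7.68% of the WGATAR sites at peak centres (7.29 to 8.09) and before 2.23% of those in flanks, a ratio of 3.44 (3.10 to 3.81). The ratio was 2.09 (1.88 to 2.33) at 7 bp and 1.59 (1.42 to 1.78) at 9 bp. Across the other 79 gaps examined for CTG on either side, it ran from 0.938 to 1.498 with a median of 1.23. The highest ratios for CAG were 1.88 (1.68 to 2.11) directly after WGATAR and 1.63 (1.45 to 1.83) at 3 bp before it. Both were above the CTG ratio at 9 bp, which did not stand apart from them. Most of the CTG at 8 bp were not part of a full E-box. CTG then WGATAR at 8 bp occurred 1309 times within peak centres, and in the form CANCTG 148 times. A further WGATAR on the opposite strand had higher ratios but fewer counts. These ratios include the general excess of WGATAR at peak centres, 3.39 by density, and were not adjusted for it. They can therefore not be compared directly with the ratios of CTG. The ratio was 6.67 (3.76 to 11.8, 70 counts at peak centres) at 2 bp after WGATAR and 6.73 (3.94 to 11.5, 82 counts) at 3 bp. The next was 5.88 (2.66 to 12.998, 48 counts) at 38 bp. A pair with both sites in the window was counted from each of them. Separate pairs were therefore fewer than these counts, and the intervals of these opposite-strand ratios are too narrow. The spacing scans were added after the data were seen.

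**Figure D5:**
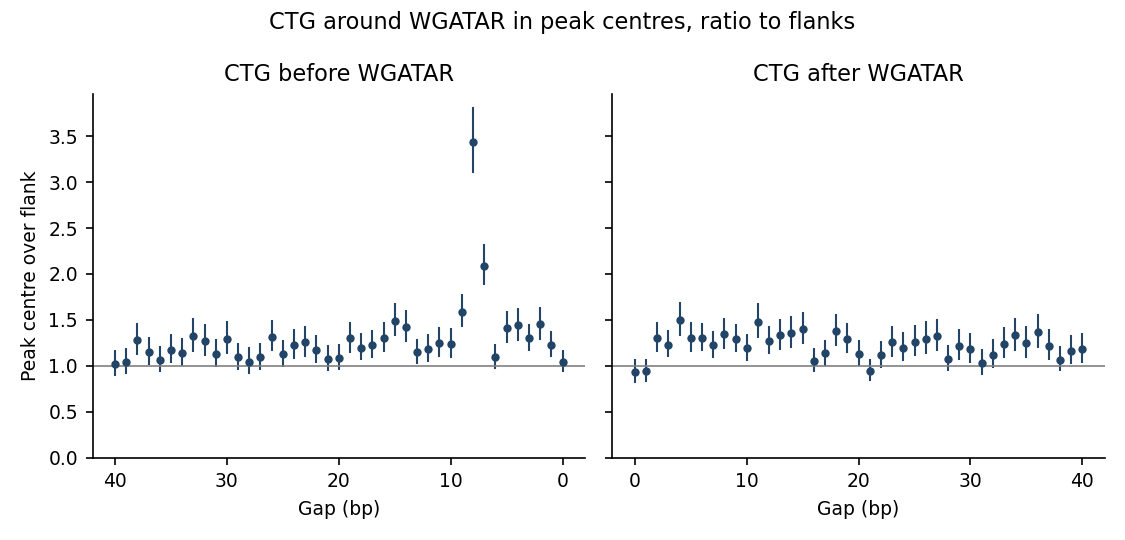
Ratio (y) of the share of WGATAR sites with a CTG at each gap in bp (x) in peak centres to that in flanks, for CTG before and after WGATAR on the same strand; points are ratios and bars 95% counting intervals. The gap of 8 bp before WGATAR stood apart, at 3.44.

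Peaks with the CTG pair at 7 to 9 bp numbered 2657 (18.5%) and had the highest median ratio of the 6 classes of motif content. It was 5.69 (5.49 to 5.80), against 5.05 (5.02 to 5.19) in the 3676 peaks with at least 2 WGATAR sites and no pair, and 4.88 (4.69 to 4.96) in the 4619 peaks with 1 site and no pair. The share of peaks with the pair went from 8.92% in the lowest quintile of ChIP reads to 25.3% in the highest. Less of the centre could be read in the lowest quintile, 88.5% against 97.3%, which lowers the share found there. The pair and the classes were not counted again in centres read in full. In peaks whose single site was TGATAA, the median ratio was 6.03 with the pair (5.69 to 6.36, 296 peaks) and 4.78 without it (4.69 to 5.02, 1221 peaks). For a single TGATAG the corresponding values were 5.66 (5.09 to 7.23, 78 peaks) and 4.69 (4.46 to 5.02). The intervals overlapped for a single AGATAA, with 5.52 (5.02 to 5.93, 523 peaks) and 4.91 (4.80 to 5.06), and for a single AGATAG, with 5.02 (4.69 to 5.69, 152 peaks) and 4.78 (4.69 to 5.02).

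Of the other partners, CACCC boxes (CCNCNCCC), bound by Krüppel-like factors such as KLF1, had a ratio of 1.40 (1.36 to 1.45). RUNX sites (TGYGGT) had 1.38 (1.33 to 1.43) and AP-1 sites (TGANTCA) 1.30 (1.22 to 1.39). ETS sites (MGGAAR), bound by factors such as PU.1 and FLI1, had 1.08 (1.05 to 1.10), close to that of E-boxes. Peak centres were also richer in GC than flanks (49.5% against 47.2%) and in CpG (16.3 against 13.4 per kb), and these ratios are not adjusted for that. CACCC boxes had a ratio of 1.42 (1.36 to 1.47) in peaks with WGATAR and 1.35 (1.26 to 1.45) in peaks where none was read, and the difference was not tested. The CTCF core (CCNNNAGGGGGCGC) occurred 6 times at peak centres, with a ratio of 2.13 and an interval of 0.811 to 5.61, so that no difference from flanks was detectable at this number.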

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

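The counts of gained and lost sites, the lane comparison, and the tests of input reads at changed bases, unread sequence, peaks close to background and read placement were chosen after the data were seen; the tests of the whole peak and of mixed bases were written before their results.

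Mismatches in the reads, which the report uses only to restore the reference sequence and to leave reads out in an alternative, showed that the cells differed from the reference at 2376 of 1468921 positions called (1.62 per kb). These differences made 76 WGATAR sites in the central 200 bp of peaks and removed 12, so that 86.4% of changes were gains (exact interval 77.4 to 92.8). Between 150 and 250 bp from the centre there were 5 gains and 4 losses (55.6% gains, interval 21.2 to 86.3), too few for a contrast with the centre. Miscalls are argued against by the input library: with bases called from ChIP reads alone, 72 sites were gained and 12 lost, and at the 24 of 73 changed positions of gained sites that input reads covered, by only 26 reads in all, 100% had the changed base in most input reads (interval 85.8 to 100). A bias of read placement as the whole cause is argued against by the 14 motifs 1 base away from WGATAR, of whose changes 55.7% were gains (50.4 to 60.9), below the interval of WGATAR though slightly above an even split. The design has no group of another genotype, so no biological explanation was tested. A candidate explanation that stays open is that the listing of a peak depends on sites the cells have, not on those of the reference.

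Peaks with no WGATAR at the centre, 23.7% of the list, were weighed against technical explanations. Unread sequence as the whole cause is argued against by the 5581 peaks read in full at the centre, of which 15.1% had no site. Sites elsewhere in the peak, or listed peaks close to background, as the whole cause are argued against less firmly. In the sequence that was read, 15.5% of all peaks had no site in their listed span. Of the 2346 peaks with a ratio of at least 10, 16.5% had none at the centre. Bases left unread raise both of these shares. The explanations were also taken jointly, in the 1254 peaks with a ratio of at least 10 and a fully read centre. Of these, 6.06% (4.80 to 7.53) had no site in the part of the listed span that was read, and 1.75% also had no GATA at the centre. Longer spans and the shorter GATA hold more sites by chance. Whether the explanations jointly account for most of the pattern can therefore not be told from these shares. Sites present by chance lower such shares. Of 129 windows of 200 bp in the flanks, 1000 bp from peak centres and read in full, 52.7% (43.7 to 61.6) had no WGATAR. Few flank windows were read in full. These are thus a small set picked by read coverage, and their share need not hold for flanks in general. No such value was computed for whole listed spans or for GATA.

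The 10 peaks with at least 30 input reads include the one with the most ChIP reads. Sequence present in more copies in the cells than in the reference could raise both libraries, and would leave mixed bases where copies differ. At well-covered positions of these peaks 0.280% (interval 0.0339 to 1.01, 2 of 715 positions) had a 2nd base in at least 10% of reads, against 0.144% (0.119 to 0.172) in the other peaks. The interval is too wide to decide, and identical copies would leave no such trace, so the origin of these peaks stays open.

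Lanes of the same group shared read positions. ChIP run 1 lane 4 and run 1 lane 8 had 8.36 times as many positions in common as after moving 1 of them by 500 or 1000 bp, each of these with run 7 lane 1 had 7.08 and 7.03 times as many, and the input lanes 5.35, while ChIP and input had 1.77 times as many. The labels do not say whether run 7 lane 1 came from a separate library preparation.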

How the results depend on the processing

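The settings with summits, fully read centres, the cells' own bases, without peaks of at least 30 input reads, and those of the CTG spacing and of gained sites were chosen after the data were seen. Of 82 alternatives, 33 stayed within the interval of the value reported (for the peak number, within 1.5 times, and for the strand shift, within 5 bp) and 49 moved outside it. A reversal of direction was looked for only in the differences between quintiles and between classes of peaks, and 0 were found. The cause of a move was not tested unless stated. The peak number was 14184 with a ratio of at least 2 and 13153 with a lower limit above 1 at 1 read per position, and strand shifts stayed within 5 bp. Depth limits the share of peaks above input, at a median of 3 input reads per peak.

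The ChIP share of reads in peaks was 2.22% at 1 read per position, 2.51% with peaks widened by 100 bp, 1.74% in peaks above the median score, 2.35% in run 1 lane 4 and 2.43% in run 7 lane 1. The input share was 0.347% without mismatches, 0.478% in widened peaks and 0.207% in peaks above the median score. The median ratio was 4.74 at 1 read per position, 4.66 without mismatches, 4.81 scaled by all reads, 5.58 and 2.68 with pseudocounts of 0.5 and 5, 6.56 above the median score, 5.22, 5.22 and 5.32 with ChIP run 1 lanes 4 and 8 and run 7 lane 1, and 4.18 and 4.27 with input lanes 1 and 2. The pseudocount weighs more with fewer reads, which also moves single lanes. Peaks above input were 91.7% at 1 read per position, 99.9% above the median score, 81.7%, 80.9% and 53.6% with the ChIP lanes, and 68.7% and 71.8% with the input lanes, where fewer reads widen the limits.

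WGATAR was in 56.9% of peaks in a 100 bp window, 84.5% over the whole peak, 88.9% as GATA alone, 45.3% as AGATAA, 84.7% above the median score, 78.9% around the summit and 84.9% with centres read in full, and in 24.2% of ChIP and 13.3% of input read sequences in peaks. The difference between the highest and lowest quintile was 17.7 points ranked by ratio, 18.1 in 100 bp and 15.1 with centres read in full, in quintiles formed anew. In 100 bp windows the ratio to flanks was 1.11 for E-boxes, 9.79 for an E-box then WGATAR and 1.45 for RUNX sites. In peaks above the median score it was 1.04, 10.02 and 1.44, and 1.57 for CACCC. CTG 8 bp before the motif had 3.82 with AGATAA, 3.88 above the median score and 2.81 below it. The gained share of changed WGATAR sites was 93.1% with at least 10 reads.

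The alternatives for transcription starts (within 5 kb, all annotated genes, better-scoring peaks) and for gene lists (1 kb, 50 kb, not matched on length, better-scoring peaks) were not run, since no annotation of build mm8 was used. No paired analysis was possible because each group has 1 library and no test was made.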

Other observations

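The comparisons in this part were chosen after the data were seen, except the shares of reads with WGATAR in peaks.

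With every GATA hidden, and among the 3058 sequences of 7 bases seen at least 300 times at peak centres, the most enriched was AGATTAG, 2.77 times as frequent as in flanks (2.53 to 3.03), followed by GATTAGC with 2.76 (2.45 to 3.11) and CTGATTA with 2.48 (2.24 to 2.74), all with GATTA in place of GATAA. WGATTA occurred at the centre of 3071 peaks (21.4%). CTG 8 bp before WGATTA was 4.05 times as dense at peak centres as in flanks (3.34 to 4.91), when WGATTA itself was 1.67 times as dense (1.60 to 1.73). The 740 peaks with WGATTA and no WGATAR had a median ratio of 4.58 (4.35 to 4.85), and the 1281 peaks with neither of these nor any GATA had 3.79 (3.68 to 4.02).

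Other sequences enriched with GATA hidden included AACCACA, which contains the core that RUNX factors bind (1.93, interval 1.80 to 2.06), CACGTGA (1.88, 1.65 to 2.14), the GC-rich CCCGCCC (1.87, 1.68 to 2.08) and CACGCCC (1.86, 1.64 to 2.10), CACACCC (1.79, 1.68 to 1.91), CAGCTGC (1.78, 1.68 to 1.90) and TGACTCA (1.70, 1.57 to 1.83). These ratios are not adjusted for the higher GC and CpG content of peak centres. E-box forms were unequal, since CAGCTG alone had a ratio of 1.61 (1.53 to 1.68) where all CANNTG had 1.07. At 8 bp before WGATAR, CAGCTG was seen 69 times at peak centres and CATCTG 59 times, against 14 and 11 times in flanks. Per WGATAR site these are ratios of 5.78 (3.25 to 10.3) and 6.29 (3.30 to 11.97), where all CANNTG had 2.98. CACCTG was seen 14 times, with a ratio of 1.82 (0.790 to 4.21) that showed no clear difference.

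CpG-rich centres, with at least 50% GC and an observed to expected CpG ratio of at least 0.6, made up 472 of the 10919 peaks with at least 90% of the centre read. They less often had WGATAR, 62.3% (57.7 to 66.7) against 81.0% (80.2 to 81.7) in the others. Yet their median ratio was higher, 6.94 (6.36 to 7.53) against 4.91 (4.85 to 5.02), with a median of 31 ChIP reads in both and of 2 and 4 input reads. Of CpG-rich centres, 36.02% had a CACCC box, against 21.6% of the others.

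Input reads were unevenly spread over chromosomes. Relative to the autosomes' median, chromosome 1 had 1.31 times the input reads per Mb, chromosome 7 had 1.23, chromosome 3 had 1.22, chromosome 10 had 0.8996 and chromosome X had 0.367. ChIP reads outside peaks gave 1.27, 1.27, 1.16, 0.877 and 0.329 for the same chromosomes.

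Of the 5 peaks with the highest ratios, MACS_peak_7224 on chromosome 2 from 28424061 to 28424574 came first, with 189 ChIP reads, 0 input reads and a ratio of 127 (lower limit 34.0). A TGATAA lay at 28424396 to 28424401, in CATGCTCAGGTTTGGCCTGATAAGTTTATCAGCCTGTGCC. MACS_peak_10484 on chromosome 5 from 121476525 to 121477213 had 289 ChIP reads, 1 input read and a ratio of 97.1 (lower limit 34.5). By lower limit it stood ahead of MACS_peak_7224, whose ratio has a finite value only because of the pseudocount of 1 read. In the pool of reads from peaks, 24.2% of ChIP reads and 13.3% of input reads had WGATAR in their 36 bases, against 7.09% and 5.69% of reads within 3 kb outside peaks.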
